A study of Arabidopsis thaliana with 6 samples.

How the data were processed

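The series holds 6 RNA-seq libraries of Arabidopsis thaliana inflorescence meristems, dissected from 15 cm tall stems after flower primordia older than the earliest stages were taken off, and 1 table per library. The authors deposited whole-number counts of reads per gene over the same 32833 loci in each table. Reads were aligned with RNA STAR, per the file headers. TAIR10 and DESeq2 are named without versions or roles, per the submitters' processing notes. The counting tool, its strand setting, its annotation and the aligner's version are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart, and reads of near-identical copies may have been split or dropped.

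Groups and replicate numbers came from the sample titles: 3 controls (reporter line) and 3 libraries labelled VGD1 (reporter line with VGD1). No library was left out. Every row named a gene, and 7374 loci had no count in any library. Totals lay between 6638772 counts (control replicate 3) and 24437872 counts, and the next lowest was 18432365. A count of 0 allows up to 3 counts, which is 0.452 CPM in control replicate 3 and 0.123 to 0.163 CPM in the others. The Poisson interval of CLV3 and the floors cover counting error only. Intervals taken from the edgeR fit also cover the spread between libraries. Pairs of libraries of 1 group differed by a chi-square of 9.2 to 23.54 per gene. The lowest value of all pairs, 8.08, was between groups, for control replicate 3 and replicate 3 labelled VGD1. No library was therefore a second copy of another. In log2 CPM, control replicate 3 correlated at 0.9657 and 0.9711 with control replicates 1 and 2. With replicates 1, 2 and 3 labelled VGD1 it correlated at 0.9617, 0.9625 and 0.9671, so it was not clearly nearer to its own group.

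Symbols and descriptions were taken from the TAIR10.1 annotation, which matched 32548 of the 32833 loci. As the name of that build differs from the one in the processing notes, no coordinates are given and it was used for names, exon length, GC content, overlaps and neighbours.

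The comparison used edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr with its default minimum count of 10 and minimum total of 15, glmQLFit with robust estimation and without the legacy mode, and the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over 19719 genes and a threshold of 0.05. CPM values carry the TMM factors. Standard errors were taken from the log2 fold change and the F statistic, and the 95% interval of VGD1 from a t distribution with 4 degrees of freedom. Sets of genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and with fry beside it: 29 lists with 487 members fixed before the data were examined, and separately 28 families defined by words of the annotation with at least 10 tested members. Some list members carry loci written down by hand where the annotation did not give exactly 1 locus for the symbol (58 of 487). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

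Genes named in the report follow a rule fixed before the data were examined: VGD1 with its neighbour; CLV3, WUS, STM and CLV1; the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 1 CPM and groups whose ranges do not overlap; and in each list up to 4 called members, or else the member with the smallest p. Further members of lists are named where a count adjusted over the list alone rests on them.

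The edgeR and camera steps were run on simulated data for 3 against 3 libraries and 19719 genes, with changed genes drawn at 3 sizes in 5 simulations. Camera called a list of 15 genes changed 1.5-fold in 5 of 5 simulations and 0 of 140 random lists of 15 genes. Genes were drawn independently of each other, so this does not test camera on lists whose members move together. The edgeR test called 26.3% (93) of genes changed 1.5-fold, 67.8% (213) of those changed 2-fold and 93.1% (296) of those changed 4-fold. It also called 79 of 96316 unchanged genes. Those 79 false calls made up a larger share of all calls than the threshold on the adjusted p allows. Genes called in the real comparison may therefore hold more false calls than that threshold states.

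Alternatives fixed before the data were examined were RLE factors, library totals, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the legacy edgeR dispersion, a log2 fold change of at least 1, the replicate number as a block, offsets for GC content and gene length with and without the block, and leaving out each library in turn. Thinning of all libraries to the shallowest and limma-voom with library weights were added after the data were seen.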

Results

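RNA was sequenced from dissected inflorescence meristems of Arabidopsis thaliana, the small domes at the shoot tip that hold the stem cells of the stem and flowers. The series describes a line in which the stem cells, marked by the CLV3 promoter, can be made to express VGD1 (VANGUARD1), a pectin methylesterase, that is, an enzyme that removes methyl groups from the pectin of the cell wall. Expression was switched on with dexamethasone through GR-LhG4, a hormone-gated transcription factor. The control line carried only the inducible reporter erTurquoise under the same promoter and was treated in the same way. There were 3 control libraries and 3 libraries labelled VGD1, all poly(A)-selected. The labels give the time between induction and harvest as 72 hours in one place and 48 hours in another, and the dexamethasone concentration as 30 µM in one and 30 mM in another. Control replicates 1 to 3 held 23210554, 24437872 and 6638772 counts, and the libraries labelled VGD1 held 19341479, 19394881 and 18432365, so control replicate 3 was the shallowest. Labels do not say that replicates came from separate batches of plants, and the p-values measure the spread between these libraries.

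The comparison asks what stem-cell expression of a pectin methylesterase changes across the meristem, and VGD1 itself was examined first. VGD1 (AT2G47040) was not higher in the libraries labelled VGD1. Its level was 9.63 ± 4.24 CPM (SD, n = 3) in the controls and 7.21 ± 0.67 CPM (SD, n = 3) in the libraries labelled VGD1. Individual libraries gave 11.4, 12.7 and 4.80 CPM in the controls against 6.59, 7.92 and 7.11 CPM. The log2 fold change was -0.57 (SE 0.25), with a 95% interval from -1.27 to 0.14. For this gene, fixed in advance, the edgeR quasi-likelihood test gave an unadjusted p of 0.0511 and an adjusted p of 0.372. That interval allows at most a 1.1-fold rise. VGDH1 (AT2G47030), the neighbouring copy of VGD1 on chromosome 2, with which reads could be shared, stood at 2.96 and 2.57 CPM. Because VGD1 does not mark the induced group, the second group is called "the libraries labelled VGD1" throughout, and every direction given here is that of labelled libraries against controls.

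CLV3 (AT2G27250), the peptide gene that marks the stem cells, had 0 counts in each of the 3 controls and 3, 8 and 11 counts in the libraries labelled VGD1. Pooled, this is 0.381 CPM (exact Poisson 95% interval 0.239 to 0.577, counting error only). Taken from the lower end of that interval, the level is at least 4.25-fold higher than 3 counts over the control group, the floor used for a total of 0. The gene fell under the expression filter. Without that filter the edgeR test gave an unadjusted p of 0.00708 and an adjusted p of 0.217. WUS, the homeobox gene that maintains the stem cells, stood at 3.67 ± 0.65 CPM in the controls and 3.01 ± 1.54 CPM in the libraries labelled VGD1 (SD; edgeR adjusted p = 0.738). STM, the homeobox gene that keeps meristem cells undifferentiated, stood at 69.3 ± 2.74 and 78.2 ± 15.8 CPM (edgeR adjusted p = 0.664). CLV1, a receptor kinase for the CLV3 peptide, stood at 51.6 ± 5.90 and 59.9 ± 2.57 CPM (edgeR adjusted p = 0.427). None of the 3 passed the test, and for CLV1 all 3 libraries labelled VGD1 lay above all 3 controls.

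**Figure D1:**
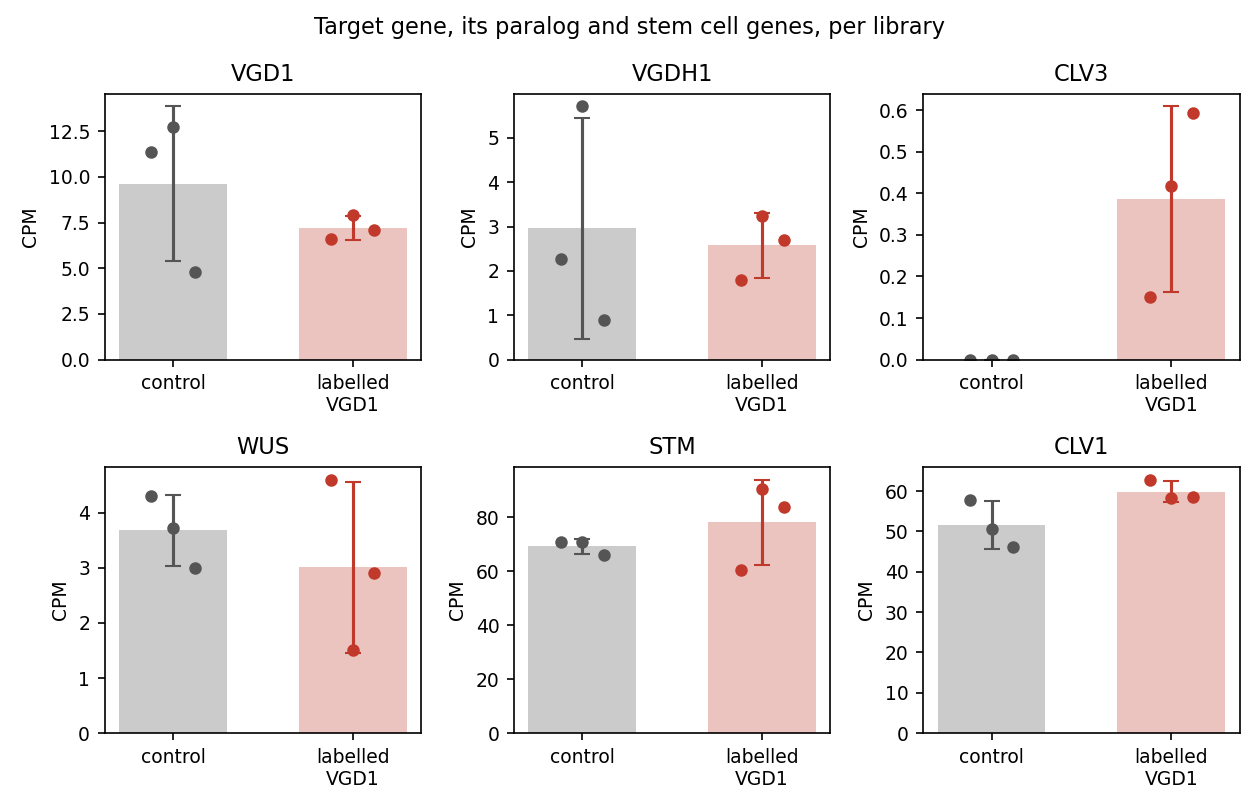
Expression in CPM (y axis, linear, from 0) of VGD1, its copy VGDH1 and the stem cell genes CLV3, WUS, STM and CLV1. Points are single libraries, bars are group means and whiskers are ± 1 SD over the 3 libraries of a group. VGD1 averages 9.63 CPM in controls and 7.21 CPM in the libraries labelled VGD1, and CLV3 is at 0 in all 3 controls.

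Among the genes that did change, the libraries labelled VGD1 had more RNA of the transcription factor genes WRKY54, WRKY70 and SPL10 and less RNA of the clock genes PRR5 and PRR9 and of the cold-regulated genes COR15A and COR15B. Of 19719 genes tested, 82 passed an adjusted p of 0.05, 20 of them higher and 62 lower. CP31B (AT5G50250), a chloroplast RNA-binding protein, showed the clearest rise, from 12.4 ± 0.19 to 51.4 ± 6.90 CPM (SD, n = 3 each), a 4.15-fold difference (edgeR adjusted p = 2.23e-04). FKF1 (AT1G68050), a blue-light receptor of the photoperiod pathway, fell from 21.2 ± 5.95 to 3.77 ± 0.84 CPM, a log2 change of -2.40 (SE 0.24, edgeR adjusted p = 0.00538). RbcX1, a chaperone for Rubisco assembly, fell from 4.44 ± 0.58 to 0.333 ± 0.18 CPM (edgeR adjusted p = 0.00538).

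WRKY54 and WRKY70, transcription factors of salicylic acid responses, both rose, by 1.93 (SE 0.27) and 0.87 (SE 0.10) on the log2 scale. WRKY70 reached 133 ± 9.74 CPM from 72.1 ± 8.20 CPM. DMR6, a salicylic acid hydroxylase, rose from 10.7 to 19.7 CPM. The receptor kinase gene RK3 rose from 13.5 to 22.9 CPM. NF-YA2 and NF-YA10, which encode A subunits of the NF-Y transcription factor, rose by 1.02 and 0.95 on the log2 scale. SPL10, a transcription factor gene of the juvenile-to-adult transition, rose from 84.9 to 140 CPM. MLP328, a major latex-like protein gene, reached 58.3 CPM from 31.0 CPM, and AACT1, an acetoacetyl-CoA thiolase gene, 45.1 CPM from 27.3 CPM. Adjusted p-values of the 9 rises other than CP31B lay between 0.0157 and 0.0442 in the edgeR test.

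PRR5 and PRR9, repressors of the circadian clock, fell by 1.68 (SE 0.20) and 0.87 (SE 0.13) on the log2 scale. The cold-regulated chloroplast protein genes COR15A and COR15B, which lie next to each other on chromosome 2 and are close copies, fell from 170 to 69.3 CPM and from 66.7 to 18.5 CPM. VSP2, a jasmonate-responsive storage protein gene, fell from 1470 ± 246 to 806 ± 43.6 CPM. LSU1, induced by low sulfur, fell from 3.09 to 0.694 CPM. YSL2, a metal-nicotianamine transporter gene, fell from 7.59 to 2.15 CPM. DOT1, a glycine-rich protein gene of vein patterning, fell from 5.47 ± 2.08 to 0.447 ± 0.37 CPM. MYB101, ABCG9 and PAP24 fell by 1.95, 2.48 and 1.73 on the log2 scale. The edgeR adjusted p-values of these named falls lay between 0.00538 and 0.0442.

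All 82 called genes had their 3 libraries labelled VGD1 outside the range of the 3 controls, as did 17.19% of all tested genes, where chance gives 10% on average. Genes can move together, so the share in a single split may lie far from 10%. That share was not computed for other splits, so 17.19% is not shown to exceed chance. Scaling by library totals alone gave 30 higher and 56 lower. The count depended on single libraries: it was 12 genes without control replicate 1, 4 without control replicate 2, 189 without control replicate 3, and 202, 85 and 45 without replicates 1, 2 and 3 labelled VGD1. The excess of lower genes did not hold in 3 of these comparisons, with 46 higher and 39 lower without replicate 2 labelled VGD1, 26 and 19 without replicate 3 labelled VGD1, and 2 and 2 without control replicate 2. Of the 24 called genes named here, CP31B and FKF1 stayed called without any 1 library. Of the 24, 5 stayed called without control replicate 1, 2 without control replicate 2 and 20 without control replicate 3. Without replicates 1, 2 and 3 labelled VGD1, 22, 14 and 8 stayed called. Adjusted p-values of the edgeR test rose up to 0.293. No sign changed, but the groups of these genes do not overlap, so leaving out 1 library could hardly change a sign. CP31B, AACT1, RbcX1, FKF1, YSL2, COR15B and PAP24 overlap a gene on the other strand in the TAIR10.1 annotation, and the strand setting of the counting is not given in the sources used here.

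**Figure D2:**
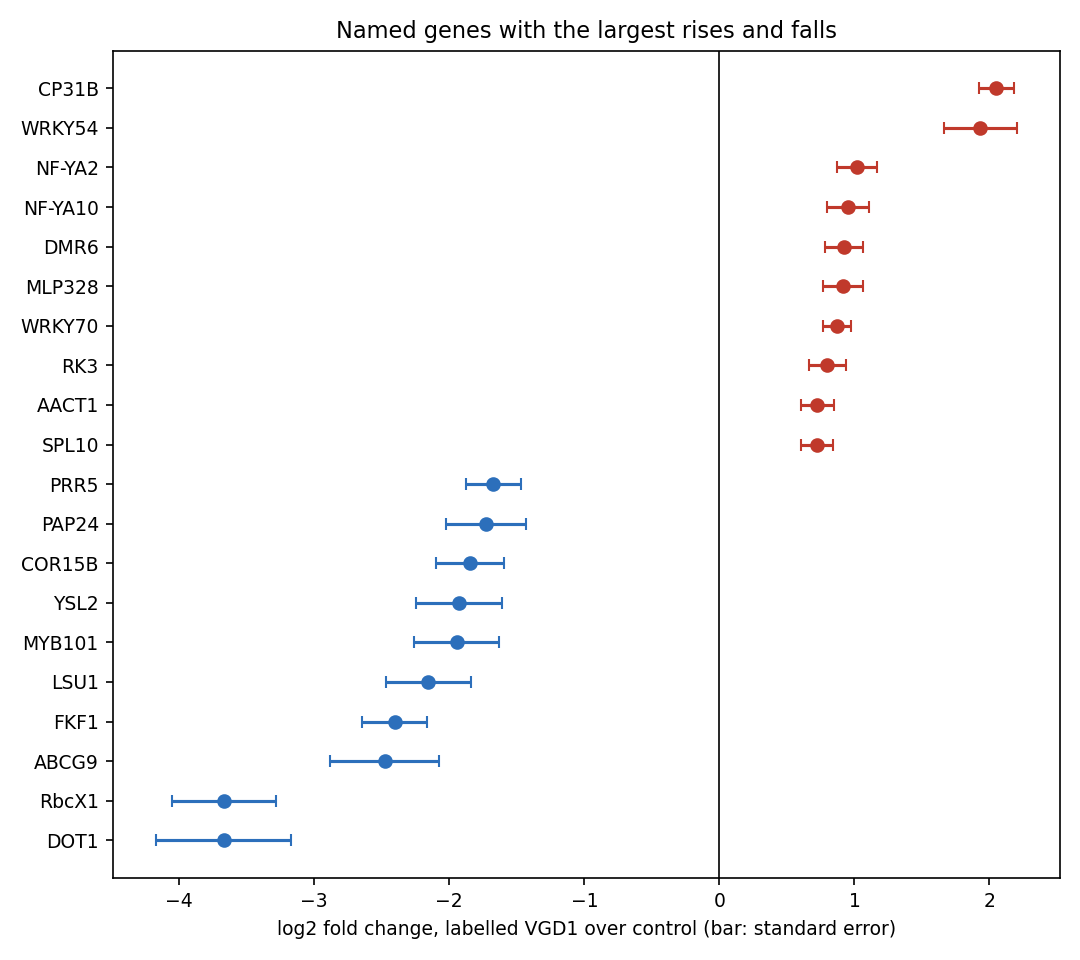
Log2 fold change of the libraries labelled VGD1 over controls (x axis) for the 10 named genes with the largest rises (red) and the 10 with the largest falls (blue). Points are edgeR estimates from 3 libraries per group and bars are standard errors. CP31B stands highest at 2.05 and FKF1 lies at -2.40.

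Cell wall genes are the subject of the study, and of the lists fixed for them 1 was lower and 1 higher in the libraries labelled VGD1. In the list of pectin methylesterase inhibitors, proteins that block enzymes of the VGD1 kind, 5 of 11 members were tested and the list was lower (camera adjusted p = 0.0134, median log2 -0.32). Its call was lost with an estimated correlation (adjusted p = 0.598), without the filter on low counts (adjusted p = 0.445) and in each of the 6 comparisons that left out 1 library (adjusted p from 0.0743 to 0.497). AT5G62360, annotated in the invertase and pectin methylesterase inhibitor superfamily, fell from 37.5 ± 7.89 to 19.6 ± 2.05 CPM (edgeR adjusted p = 0.0484). That gene was called in 9 of 20 alternatives (highest adjusted p 0.262, without control replicate 2; log2 fold change from -1.033 to -0.764). It was the 1 member called over all genes, and 2 members, AT5G62360 and AT1G62770, were lower adjusted over the list alone. No member of the list of other pectin methylesterases passed the test, and PME3, with the smallest p, stood at 107 and 81.2 CPM (edgeR adjusted p = 0.181, list adjusted p = 0.281). The list of cell wall integrity receptors and RALF peptides was higher (camera adjusted p = 0.0428, median log2 0.06) with no member called over all genes and 2, WAK1 and WAK2, higher adjusted over the list alone. That call ended with an estimated correlation (adjusted p = 0.598), and also without control replicate 2 (0.05), control replicate 3 (0.0949) or replicates 1, 2 or 3 labelled VGD1 (0.086, 0.188 and 0.0582). WAK1, a wall-associated kinase, stood at 34.0 ± 9.22 and 62.5 ± 8.15 CPM (edgeR adjusted p = 0.127). Pectin synthesis and breakdown (QUA1 at 124 and 145 CPM), primary-wall cellulose and xyloglucan synthesis (CESA5 at 232 and 273 CPM) and expansins with xyloglucan endotransglucosylases (EXPA8 at 15.7 and 8.04 CPM, the 1 member lower adjusted over the list alone) were not called, with list adjusted p-values of 0.874, 0.298 and 0.571.

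Organ boundary genes were higher as a list (camera adjusted p = 0.0428, median log2 0.26, 10 of 12 members above 0), with no member called over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.598. The call also ended without control replicate 2 (adjusted p = 0.393) or replicates 1, 2 or 3 labelled VGD1 (0.0959, 0.0944 and 0.0582), and with library totals alone, DESeq2 statistics or thinned libraries (0.0598, 0.0606 and 0.053). LSH3, the member with the smallest p, stood at 9.32 ± 1.92 and 13.7 ± 1.95 CPM (edgeR adjusted p = 0.196). Stem cell and meristem regulators were not called as a list (adjusted p = 0.26, 18 of 26 members above 0), although the list was higher without the filter on low counts (adjusted p = 0.0391) or without control replicate 3 (adjusted p = 0.0458). HEC3, a bHLH gene of the meristem, stood at 1.48 ± 0.32 and 0.340 ± 0.32 CPM (edgeR adjusted p = 0.179).

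Among hormone and stress lists, jasmonate genes were lower (camera adjusted p = 5.71e-05), abscisic acid and drought genes were lower (5.96e-04) and touch and early wound genes were higher (0.0134). With an estimated correlation none of the 3 was called, at adjusted p-values of 0.598, 0.598 and 0.68. The jasmonate list had a median log2 of -0.32 with 15 of 18 members below 0. VSP2 was called over all genes, and 6 members were lower adjusted over the list alone, among them LOX2 and the repressors JAZ1 and JAZ6. The abscisic acid and drought list had a median log2 of -0.34 with COR15A called over all genes, and 5 members lower and HAI1 higher adjusted over the list alone. Library means of both lists overlapped between groups. Relative to the mean of the 6 libraries, control replicate 3 lay below replicate 1 labelled VGD1 in the jasmonate list (-0.17 and 0.014) and the abscisic acid list (-0.096 and 0.063). Touch and early wound genes had a median log2 of 0.17 and 14 of 16 members above 0, with no member called over all genes or adjusted over the list alone. CBF2 stood at 19.8 ± 7.74 and 28.8 ± 0.96 CPM (edgeR adjusted p = 0.396). The touch list had its lowest mean in control replicate 3, the shallowest library, and its call ended without that library (adjusted p = 0.618) or without replicate 1 labelled VGD1 (0.212).

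Clock genes were lower as a list (camera adjusted p = 0.00368, median log2 -0.07). The call was lost with an estimated correlation (adjusted p = 0.598) and without replicate 3 labelled VGD1 (adjusted p = 0.189). Of 13 members 7 lay below 0 and 6 above. PRR5 and PRR9 were called over all genes, and PRR5, PRR9, ELF4 and GI were lower adjusted over the list alone. Defence genes were not called as a list (adjusted p = 0.343), although EDS1 (50.8 ± 1.13 and 72.8 ± 9.54 CPM, edgeR adjusted p = 0.0828) and PAD4 were higher adjusted over the list alone. Heat shock genes were not called either (adjusted p = 0.269), with HSFA2 at 1.81 and 3.10 CPM.

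Lists of genes from tissues outside the meristem dome were lower in the libraries labelled VGD1: photosynthesis genes (camera adjusted p = 3.68e-10), tapetum and anther genes of older flowers (2.95e-06) and vascular and secondary-wall genes of the stem (7.72e-04). With an estimated correlation none was called (adjusted p = 0.598 for each of the 3). All 21 photosynthesis genes lay below 0 (median log2 -0.36), as did 15 of 16 tapetum genes (median -0.76) and 17 of 19 vascular genes (median -0.42). No member of the 3 lists passed the test over all genes. Adjusted over the list alone, 2 photosynthesis genes, 0 tapetum genes and 6 vascular genes were lower. CA1, a carbonic anhydrase gene, stood at 386 ± 97.6 and 230 ± 14.8 CPM (edgeR adjusted p = 0.129), the tapetum gene A7 at 83.8 ± 38.8 and 30.1 ± 8.00 CPM (edgeR adjusted p = 0.214), and SUC2, a sucrose transporter gene of phloem companion cells, at 68.5 ± 7.17 and 47.7 ± 4.16 CPM (edgeR adjusted p = 0.0722). The vascular call ended without replicate 1 labelled VGD1 (adjusted p = 0.086). Library means of the tapetum list overlapped between groups, since replicate 1 labelled VGD1 lay 0.373 above the mean of the 6 libraries on the log2 scale and replicate 2 lay at -1.188. Photosynthesis and vascular lists had their lowest means in replicate 1 labelled VGD1 (-0.327 and -0.443), where the jasmonate, abscisic acid and clock lists lay at 0.014, 0.063 and 0.057. Groups overlapped there too: control replicate 3 lay below replicate 2 labelled VGD1 in the photosynthesis list (-0.136 and -0.038) and the vascular list (-0.074 and 0.108). The photosynthesis genes moved together (estimated correlation 0.9106), so 21 genes below 0 are not 21 separate observations.

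**Figure D3:**
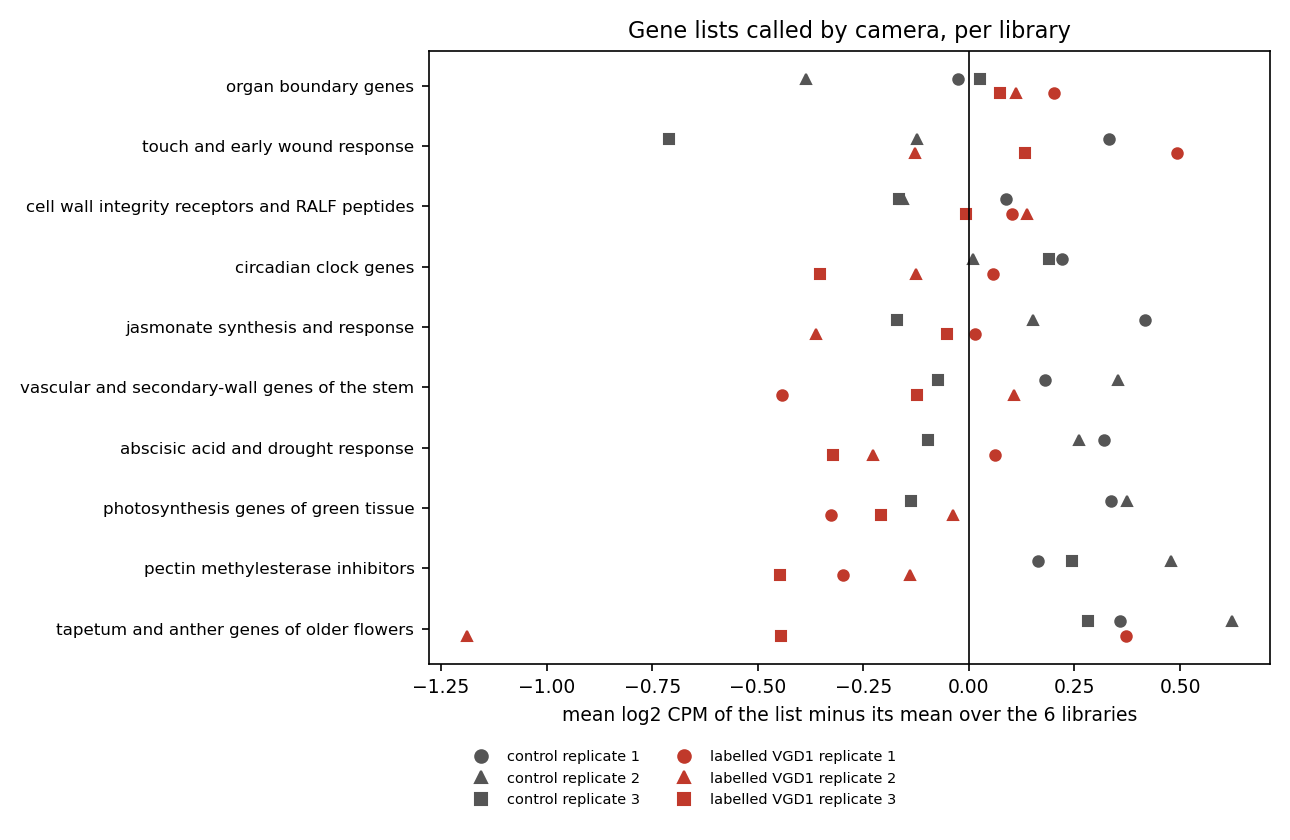
Mean log2 CPM of each called gene list minus its mean over the 6 libraries (x axis), 1 row per list, controls in grey and libraries labelled VGD1 in red, with a marker shape per replicate number. Groups are apart for the pectin methylesterase inhibitors and the organ boundary genes and overlap for the other 8 lists, including tapetum genes, where replicate 1 labelled VGD1 lies at 0.373.

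The other lists were not called, and over the 29 lists the 19 without a call had adjusted p-values from 0.103 to 0.903. Besides the stem cell list, 7 of them were called in some alternatives that test for 1 direction: heat shock genes higher in 4, defence, lateral organ and primary-wall synthesis genes higher in 2 each, G1 and DNA replication genes and flowering-time genes higher in 1 each, and floral identity genes lower in 1 (lowest adjusted p 4.83e-04, floral identity genes without replicate 1 labelled VGD1). The fry test for changes in either direction called 4 of the 19, cytokinin synthesis, brassinosteroid, flowering-time and defence genes (adjusted p from 0.00777 to 0.0136). LOG1, a cytokinin-activating enzyme gene, was the member with the smallest p of the cytokinin synthesis, breakdown and perception list (33.1 ± 6.05 and 21.1 ± 2.74 CPM, edgeR adjusted p = 0.0931, list adjusted p = 0.504). Of that list 1 member was higher and 1 lower adjusted over the list alone. Among type-A cytokinin response regulators, ARR7 stood at 22.5 and 28.4 CPM (list adjusted p = 0.874). Auxin synthesis, transport and patterning had PID, a kinase gene of flower initiation, at 68.4 and 101 CPM (list adjusted p = 0.357), and the Aux/IAA and GH3 list had IAA18 at 41.9 and 48.6 CPM (list adjusted p = 0.466). Gibberellin and brassinosteroid lists each had an adjusted p of 0.553 and 1 member lower adjusted over the list alone, GASA4 at 275 and 196 CPM and PRE1 at 14.7 and 7.10 CPM.

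SVP, a floral repressor gene, stood at 23.2 ± 0.47 and 39.5 ± 7.18 CPM and narrowly missed the threshold (edgeR adjusted p = 0.0510), in an inflorescence and flowering-time list that was not called (adjusted p = 0.26) and in which SVP was the 1 member higher adjusted over the list alone. LFY, the floral identity gene, stood at 21.3 and 30.5 CPM (edgeR adjusted p = 0.152, list adjusted p = 0.570). KAN2 of the lateral organ list stood at 21.2 and 27.2 CPM (list adjusted p = 0.103), and ATML1 of the epidermal list at 172 and 210 CPM (list adjusted p = 0.172). Cell division lists were not called, with CDKB1;1 at 26.2 and 29.9 CPM (mitosis list adjusted p = 0.903) and CYCD3;3 at 69.1 and 83.1 CPM (list adjusted p = 0.281). Median, mean and test differed in sign for 9 lists, none of them called: stem cell regulators, both cytokinin lists, Aux/IAA genes, gibberellin, brassinosteroid, pectin synthesis, expansins and defence genes.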

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

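Thinning and limma-voom with library weights were chosen after seeing the data. Of the 20 genes higher and 62 lower, the counts became 32 higher with RLE factors, 43 and 96 without a filter, 136 and 288 with DESeq2, 39 lower with the legacy dispersion, 7 and 37 at a log2 fold change of at least 1, 33 lower in libraries thinned to the shallowest, and 79 and 185 with library weights, and the causes were not tested except that the fold threshold only removes genes and thinning removes counts. Leaving out 1 library gave 2 to 46 higher and 2 to 165 lower, with 4 genes in all without control replicate 2 and 202 without replicate 1 labelled VGD1. DESeq2 called 82 of the 82 genes, limma-voom 67, the legacy dispersion 53 and thinned libraries 42. Each alternative kept the sign of every one of the 82 that it tested. The groups of all 82 do not overlap, so that outcome was nearly fixed in advance and says little about stability. Equal replicate numbers did not mark shared deviations (correlations of -0.01, 0.033 and 0.095, and replicates 1 and 2 correlated better with another number), and a replicate block gave 75 higher and 119 lower, 68 and 110 with a GC offset and 70 and 113 with a length offset. Lists called, 3 higher and 7 lower, became 0 and 0 with an estimated correlation (adjusted p from 0.598 to 0.68) and 0 and 0 with fry (lowest adjusted p 0.331, with 2 lists at an unadjusted p under 0.05), while fry's test for changes in either direction called 8 lists. There were 5 lists higher without a filter and 1 higher with the replicate block, where the organ boundary list had an adjusted p of 0.059 and the cell wall integrity list 0.0538. Leaving out 1 library gave 2 to 5 lists higher and 5 to 6 lower. The inhibitor list had under 5 members, and no test, with the 1 CPM filter and in thinned libraries. No named gene or list changed direction while called, and 1 uncalled named gene changed sign in 1 alternative. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In the edgeR test the real split called 82 genes, and it was the only 1 of the 10 to reach that number. The highest of the others was 0, with 387 to 1846 genes at an unadjusted p under 0.05 against 2677. Each of the others mixes both groups, so a difference between the groups would add to its spread and hold its calls down. The 0 therefore says little about chance. Depth limits low genes such as CLV3, for which control replicate 3 could hold up to 0.452 CPM unseen.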

Other observations

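The tests of reads shared with VGDH1, of CLV3 promoter activity, of exchanged labels and of the green tissue share with widened intervals were chosen after their results were seen. Families defined by words of the annotation are described here relative to controls, in the libraries labelled VGD1. By camera 3 families were higher and 6 lower, and all of these calls were lost with an estimated correlation. Adjusted p-values were then 0.545 for the kinases, WRKY genes, lipid transfer wording, polygalacturonases and peroxidases. They were 0.618 for the pectinesterase wording and 0.755 for the ethylene response factors, ribosomal proteins and chloroplast loci. Receptor-like kinase and leucine-rich repeat genes were higher, with 168 of 243 above 0 (camera adjusted p = 6.95e-05, median log2 0.12), as were WRKY genes (28 of 46 above 0, adjusted p = 0.00212) and ethylene response factors (13 of 18, adjusted p = 0.0309). Genes annotated with lipid transfer were lower (41 of 51 below 0, camera adjusted p = 5.47e-06, median log2 -0.34). Of these 51, 37 have the word inhibitor in their annotation, so not each need be a lipid transfer protein. Also lower were polygalacturonases and pectin lyases (43 of 59, adjusted p = 0.00309), peroxidases (36 of 53, adjusted p = 0.0110), ribosomal proteins (233 of 314, adjusted p = 0.00424, median log2 -0.06) and chloroplast-encoded loci (53 of 73, adjusted p = 0.0103). Genes annotated with pectinesterase or pectin methylesterase were lower too (37 of 52, adjusted p = 0.0103). Of these 52, 42 have the word inhibitor in their annotation, among them the enzyme VGD1. The word therefore does not part inhibitors from esterases. The fixed esterase list holds 14 of the 52 and the fixed inhibitor list 5. The fixed tapetum and anther list, which shares 2 genes with the lipid transfer family, had a median log2 of -0.76 with 15 of 16 below 0, and the photosynthesis list -0.36 with 21 of 21 below 0 (adjusted p = 0.598 for each with an estimated correlation).

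Among called genes outside the naming rule, chosen after their values were seen, GRP7, an RNA-binding protein gene under clock and cold control, fell from 1049 to 405 CPM (edgeR adjusted p = 0.0346), and RCI2A, a low-temperature and salt response gene, from 40.5 to 16.2 CPM (edgeR adjusted p = 0.00538). The lectin gene AT5G03350 rose from 20.5 to 60.6 CPM (edgeR adjusted p = 0.00538), and AT5G66910, annotated as a disease resistance protein, from 16.8 to 29.8 CPM (edgeR adjusted p = 0.0266). The glucosinolate pathway genes SOT18 and FMO GS-OX2 fell by 0.89 and 0.86 on the log2 scale (edgeR adjusted p = 0.0449 and 0.0378).

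VGD1 was not higher in the libraries labelled VGD1 (log2 -0.57). Reads diverted to VGDH1 are argued against only as cover for a rise above 0.316 on the log2 scale. That is the upper 95% bound for the summed counts of both genes. A smaller rise, or reads dropped because both copies match them, would not show in that sum. A low activity of the CLV3 promoter in the dissected tissue stays open: CLV3 counts were at most 0.0833 of the VGD1 counts in any library. Pollen RNA carrying endogenous VGD1 also stays open, since 11 tested pollen genes had a median log2 fold change of -0.406, between 0 and the -0.57 of VGD1, and the summed level of all 16 pollen genes looked at, 5 of them untested, was 29.5 to 43.8 CPM in the controls and 30.0 to 37.7 CPM in the libraries labelled VGD1. An exchange of the labels of the 2 groups, which would turn every direction given, also stays open. VGD1 was 1.48-fold higher in the controls (log2 -0.566, edgeR unadjusted p = 0.0511, adjusted p = 0.372). That difference came from control replicates 1 and 2 (11.4 and 12.7 CPM). Control replicate 3 had the lowest level of the 6 libraries (4.80 CPM, against 6.59, 7.92 and 7.11 CPM in those labelled VGD1). A wrong label on 1 library was not tested. A transgene not counted at the VGD1 locus was not tested.

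PRR5, PRR9, FKF1, COR15A and COR15B were lower in the libraries labelled VGD1, while 6 of 13 members of the clock list lay above 0 and that list's call was lost with an estimated correlation (adjusted p = 0.598). For a lower share of green tissue, the 21 photosynthesis genes had a median of -0.359 (quartiles -0.447 and -0.255). That was nearer 0, by more than their quartile range, than -0.65, which is 1/2 of the median of PRR5, PRR9 and COR15A. Those 3 genes were picked because they were called lower, which can overstate their fall. All 25 tested clock and abscisic acid genes had a median of -0.157. The comparison therefore does not decide whether a lower share of green tissue is the whole cause. Intervals were then widened for the selection of called genes. The upper bounds of FKF1, COR15A and PRR5 (-1.037, -0.542 and -0.459) still lay below the lower quartile of the photosynthesis genes, PRR5 narrowly. Those of 2 genes, PRR9 and COR15B (-0.140 and -0.136), did not. The quartile was taken as fixed, although the photosynthesis genes moved together (estimated correlation 0.9106). A lower share of green tissue thus stays open, at least for PRR9 and COR15B. A difference in time of day at harvest may contribute: 4 morning genes had a median log2 change of 0.299 and 6 evening genes -0.313, a difference of 0.612. The exact two-sided permutation p across genes was 0.119, and genes are not independent replicates. PRR5, PRR7 and PRR9 of the clock list were in neither set, PRR5 and PRR9 because their fall had been seen before. Of the morning genes, CCA1 and LHY moved little (0.049 and 0.212, edgeR adjusted p = 0.960 and 0.877), and RVE1 and RVE8 lay at 0.690 and 0.386. The evening genes TOC1 and BOA lay higher (0.601 and 0.064), while the other evening genes lay lower. An effect of the introduced line itself was not tested and stays open.

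At 2 loci the libraries of 1 group were nearly without counts: AT3G01345, an uncharacterized gene on chromosome 3, at 472 CPM in controls and 1.40 CPM in the libraries labelled VGD1 (edgeR adjusted p = 1.81e-05), and AT2G06995, annotated as other RNA on chromosome 2, at 31, 35 and 8 counts in controls and 0 in the others. A linked stretch of another genetic background in 1 line may be a source of such differences, and called genes formed 9 pairs within 100 kb, against a median of 6 and a 95th percentile of 11 in 10000 random draws. That count does not decide it, and no close pair held either of the 2 loci. An effect of the line's transgene was not tested.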
